A study of Mus musculus with 4 samples.

How the data were processed

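RNA from 4 samples of DS19 mouse erythroleukemia cells was sequenced on an Illumina HiSeq instrument, after ribosomal RNA had been depleted, per the labels' protocols. There were 2 libraries of wild-type and 2 of Wdr26 knockout cells, grouped by the genotype in the labels, with the numbers 1 and 2 taken from the sample titles. Whether the library preparation kept strand is not given in the sources used here, so values of genes that overlap a neighbour in the gene table, such as Alas2, B2m and Ranbp10, are uncertain.

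The authors deposited a single table with 1 value per gene and library. Its header names no unit, and the values were identified as FPKM from the deposited numbers themselves. Multiplied by transcript length, each library summed to between 1.02e+09 and 1.04e+09, as FPKM does, while the plain totals differed between libraries (621900, 672000, 634900 and 645400 in wild-type libraries 1 and 2 and knockout libraries 1 and 2). TopHat2 and the mm10 genome are named in the submitters' processing notes, without a version or role, and the program that computed the values is not given in the sources used here. The table lists RefSeq transcripts and, per the file headers and identifiers, transcripts assembled from the reads, which supply 1041 of the 17393 genes. Assembled transcripts are also part of the values of Wdr26, Muc13, Slc22a17, Vegfa and M1ap. In the lowest values of short genes with a single transcript, steps worth 1 fragment gave an estimated depth of 27300000, 28600000, 28000000 and 27100000 fragments for the same libraries. These estimates assume a loss of 200 bases of effective length and are approximate, and no confidence interval from counts was computed. Depth therefore differed little between genotypes.

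Gene symbols were used as deposited. Symbols that a spreadsheet had turned into dates (24) were restored through the gene ID, and 16316 gene IDs matched the mouse RefSeq gene table of assembly GRCm38.p6 (mm10), from which coordinates were taken. The table holds 0 mitochondrially encoded genes, and 1074 genes are at 0 in every library. A value of exactly 0 can be a failed estimate, so such genes are only said to be listed at 0. Transcript lengths and GC content came from GENCODE M21 transcripts through RefSeq identifiers.

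Values were converted to log2(FPKM + 1), and genes with at least 1 FPKM in at least 2 libraries were kept (10670 genes). Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, without covariates), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes without a log scale are ratios of group means of FPKM. With 2 libraries against 2 an exact permutation test cannot give a p below 0.333, so none was run on single genes. Tables were prepared with pandas and figures with matplotlib.

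The gene lists (30, of which 25 had at least 3 tested members) were fixed before the data were examined, together with the test, the alternatives and the rule for naming genes. The lists cover the CTLH ligase, erythroid genes, the nuclear envelope, chromatin, the cell cycle, metabolism, stress, immune genes and markers of other cell types. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the 25 lists. The test was repeated with an estimated correlation and with fry. With an estimated correlation, camera takes its degrees of freedom from the residuals of the 4 libraries, so few lists can pass. The rule named Wdr26, then, among genes past the threshold with a mean of at least 1 FPKM and groups that did not overlap, the 8 with the largest rise and the 8 with the largest fall. It also named up to 4 members past the threshold per list, filled up to 2 with the most abundant members, and every measured member of the globin, lamina and CTLH lists. Some genes that the rule names are not reported here. Genes named beyond this rule were chosen after their values were seen: those past the threshold only within their own list, a neighbour that overlaps Tmem176b, and the further genes described under other observations.

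The alternatives were median-centred values, quantile normalization, no filter on low genes, a mean of at least 5 FPKM, limma without the trend, a pseudocount of 0.1, the library number as a block, leaving out each library in turn, a test against a log2 change of 1 (treat), and leaving out 11 globin genes with the totals rescaled. Fits that combined the block with median-centred values or with the stricter filter were added after the data had been seen.

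The procedure was tested on simulated data for knockout against wild type, with 200 changed genes in each of 10 runs over about 10563 tested genes. The changed genes were drawn only from genes above about 5 FPKM in wild type, so recovery at lower levels was not measured. With noise independent between libraries it recovered 1.6% of genes changed 1.5-fold, 38.4% of those changed 2-fold, 76.2% of those changed 4-fold and 90.6% of those changed 8-fold, with on average 2.5 false calls among 105.9. With noise shared by libraries of the same number it recovered 0%, 38.4%, 78.4% and 91.8%, with 0.1 false calls among 104.4. The list test, simulated with noise independent between libraries and between genes, called 0 of 250 unchanged lists. It found a list shifted by −0.3 in 10 of 10 runs. Simulated list members were thus uncorrelated, while correlations estimated in the data were 0.20 for heme, 0.35 for globins and 0.98 for replication. The simulation therefore cannot show how often correlated members give false list calls.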

Results

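RNA was sequenced from mouse erythroleukemia (MEL) cells of the DS19 line, a transformed erythroid precursor line that dimethyl sulfoxide can drive toward a red cell-like state. The 4 libraries comprised 2 from wild-type cells and 2 from cells in which Wdr26 had been knocked out, numbered 1 and 2 in each genotype. The labels name 1.5% dimethyl sulfoxide in the culture description but do not say whether the sequenced cells had received it. Expression was measured as FPKM (fragments scaled to transcript length and to sequencing depth) for 17393 genes. The size of the smallest steps in the values corresponded to about 27300000 and 28600000 fragments in wild-type libraries 1 and 2, and to about 28000000 and 27100000 in knockout libraries 1 and 2. Between 10416 and 10603 genes reached 1 FPKM in a library. Alpha globin (Hba-a1) alone made up 21.8% and 25.1% of the summed FPKM in wild type and 19.2% and 22.5% in knockout. Across the 10670 genes tested, the SD of the log2 difference between libraries was 0.27 for the wild-type pair and 0.36 for the knockout pair. Between genotypes it was 0.31 for the libraries numbered 1 and 0.33 for those numbered 2. It was 0.44 between wild-type library 1 and knockout library 2, and 0.36 between wild-type library 2 and knockout library 1. Each knockout library was thus closer to the wild-type library of its number than to the other knockout library. Nothing in the labels says that the libraries of a genotype came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

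The series compares knockout with wild-type cells, and the targeted gene was examined first. Wdr26 (gene ID 226757, chromosome 1, 181173226 to 181220921, mm10) encodes a WD40-repeat subunit of the CTLH E3 ubiquitin ligase. It stood at 55.4 and 52.4 FPKM in the wild-type libraries and at 9 and 7.84 FPKM in the knockout libraries. The knockout mean of 8.42 ± 0.820 FPKM (SD, n = 2) was 15.6% of the wild-type mean of 53.9 ± 2.11 FPKM (SD, n = 2). On the log2(FPKM + 1) scale the change was −2.55 with a standard error of 0.14 (limma, Benjamini-Hochberg adjusted p = 0.0063). The values are sums over the whole gene and do not show which part of the transcript remained. The adjusted p rose to 0.0675 when low genes were not filtered out, 0.0682 without wild-type library 1 and 0.0549 without wild-type library 2.

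Besides Wdr26, 4 genes fell and 5 rose in the knockout. The surface mucin gene Muc13 and Slc22a17, which encodes a receptor for lipocalin-2, fell from moderate levels to nearly undetected ones. Vegfa, which encodes the endothelial growth factor VEGF-A, was abundant and fell to 35.8% of its wild-type mean. The genes that rose were Tnni3 (cardiac troponin I), Pdgfb (the B chain of platelet-derived growth factor), M1ap (a meiosis-associated protein), Lgals3bp (a secreted galectin-3 binding protein) and Tmem176b (a membrane protein). For each of these genes both knockout libraries lay on the same side of both wild-type libraries, which the rule for naming them required.

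Among the genes that fell, Muc13 (gene ID 17063, chromosome 16, 33794037 to 33819929) went from 9.19 and 9.21 FPKM to 0.13 and 0.29 FPKM, a log2 change of −3.08 (SE 0.16, limma adjusted p = 0.0063). Slc22a17 (gene ID 59049, chromosome 14, 54906727 to 54913132) went from 7.15 and 7.5 FPKM to 0.21 and 0.11 FPKM, a log2 change of −2.84 (SE 0.16, limma adjusted p = 0.0063). Vegfa (gene ID 22339, chromosome 17, 46016993 to 46032377) averaged 245 ± 16.1 FPKM in wild type and 87.9 ± 4.50 FPKM in knockout (SD, n = 2), with a log2 change of −1.47 (SE 0.13, limma adjusted p = 0.035). The remaining gene that fell, BGI_novel_G000626, is an unnamed locus built from assembled transcripts, and it was listed at 7.06 and 5.50 FPKM in wild type and at 0.12 and 0 FPKM in knockout (limma adjusted p = 0.0112). Because a pseudocount of 1 was added, the log2 changes understate the change of genes with low values.

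Tnni3 (gene ID 21954, chromosome 7, 4518305 to 4522718) was the most abundant gene that rose, from 44.5 ± 3.55 FPKM to 207 ± 4.12 FPKM (SD, n = 2), 4.65-fold (log2 change 2.20, SE 0.13, limma adjusted p = 0.0066). Pdgfb (gene ID 18591, chromosome 15, 79995865 to 80024614) was listed at 0.74 and 0.83 FPKM in wild type and at 6.79 FPKM in both knockout libraries (log2 change 2.13, SE 0.15, limma adjusted p = 0.013). M1ap (gene ID 110958, chromosome 6, 82946908 to 83030309) went from 1.03 and 0.75 FPKM to 7.16 and 6.12 FPKM (log2 change 2.02, limma adjusted p = 0.0311). Lgals3bp (gene ID 19039, chromosome 11, 118392747 to 118401959) rose 5.75-fold, from 6.34 and 4.74 FPKM to 37.2 and 26.6 FPKM (log2 change 2.32, limma adjusted p = 0.035). Tmem176b (gene ID 65963, chromosome 6, 48833811 to 48845948) rose 2.55-fold, from 17.6 and 18.8 FPKM to 47.3 and 45.3 FPKM (log2 change 1.30, limma adjusted p = 0.0479). Tmem176b overlaps Tmem176a on the opposite strand, so reads of the pair may be shared. Tmem176a, named only because of that overlap, went from 7.46 and 9.40 FPKM to 21.99 and 27.89 FPKM without passing the test (limma adjusted p = 0.0803).

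**Figure D1:**
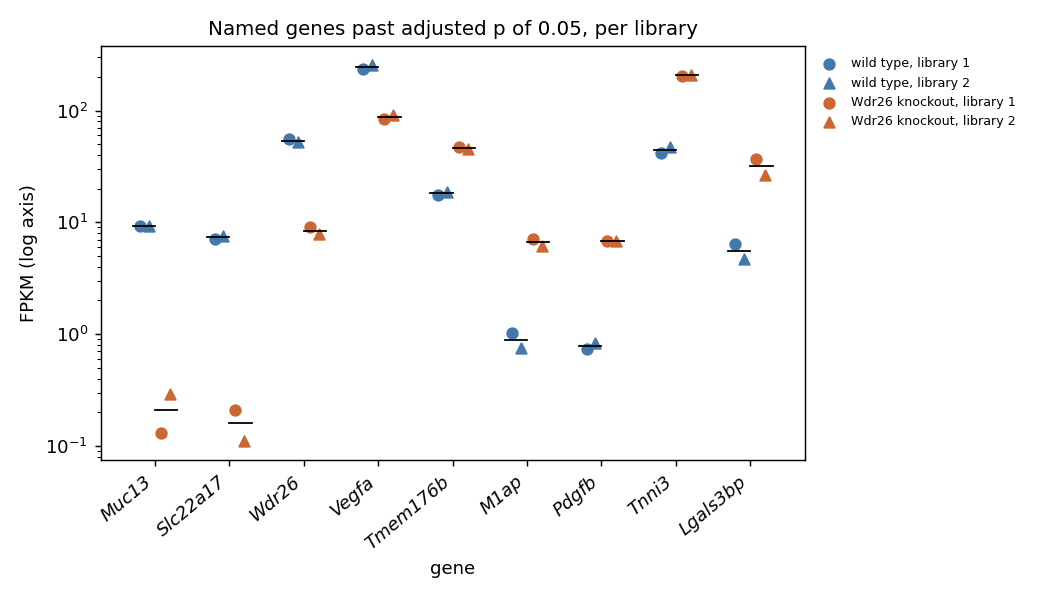
FPKM of the 9 named genes past an adjusted p of 0.05 in each library, on a log axis, with wild type in blue, knockout in orange, library 1 as circles and library 2 as triangles. Black lines mark the mean of each genotype, and the libraries of a genotype lie close together beside the distance between genotypes, as for Tnni3 at 42.0 and 47.0 against 204 and 210 FPKM.

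In all, 10 of the 10670 genes passed (limma on log2(FPKM + 1), adjusted p under 0.05), 5 higher and 5 lower in knockout. At an unadjusted p under 0.05 there were 1218 genes, against 533.5 by chance. The split of the same libraries by number gave 1503. Groups did not overlap for 3195 genes that were higher in both knockout libraries and 1149 that were lower, 40.7% of the genes tested, where chance gives 33.3% for 2 against 2. The balance depends on scaling: with median-centred values, counted after the first counts were seen, 2127 were higher and 2148 lower. Of the genes without centring, 134 were at least 2-fold higher and 76 at least 2-fold lower. The chance values of 533.5 genes and 33.3% assume interchangeable libraries, whereas same-numbered libraries deviated together, so neither is exact here. With the globin genes left out and the totals rescaled, 21 genes passed, 7 higher and 14 lower. Without the filter on low genes 0 passed, and with a mean of at least 5 FPKM 2 passed. With the library number as a block 1863 passed, in a fit with 1 residual degree of freedom per gene. No gene passed in limma without wild-type library 1 or without wild-type library 2 (574 genes at an unadjusted p under 0.05 in each), and 720 and 314 passed without knockout library 1 and without knockout library 2.

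Genes of the red cell program were lower in the knockout as groups in camera with a preset correlation between genes of 0.01, but not with an estimated correlation (adjusted p = 0.558 for each list). The lists were those of globins and their chaperone (preset adjusted p = 5.24e-06), of heme synthesis and iron uptake (3.85e-07) and of the red cell membrane and skeleton (0.000127). Their median log2 changes were −0.34 over 10 genes, −0.21 over 20 genes and −0.17 over 23 genes. The largest change in the 3 lists was that of Slc4a1, the band 3 anion exchanger of the red cell membrane, which stood at 436 and 285 FPKM in wild type and at 48.6 and 6.70 FPKM in knockout.

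The mean level of each of these lists relative to all genes was lower in both knockout libraries than in both wild-type libraries. That also held for the mitosis, transcription factor, enucleation, glycolysis, cholesterol, p53 target and cell-cycle exit lists. With single libraries left out, the globin median ran from −0.47 (without wild-type library 1) to −0.16 (without wild-type library 2), the heme median from −0.30 (without wild-type library 2) to −0.11 (without wild-type library 1), and the membrane median from −0.25 (without knockout library 1) to −0.095 (without knockout library 2) and −0.098 (without wild-type library 1). With a mean of at least 5 FPKM the globin median was −0.18.

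Within the globin list, no member passed over all genes, and 2 passed when adjusted over the list alone, both lower. These were the embryonic beta-like globin gene Hbb-y, at 6.92 and 8.02 FPKM in wild type and 1.94 and 1.31 FPKM in knockout, and Hbq1a, a theta-like globin gene, at 15.2 and 18.4 FPKM and 6.67 and 3.94 FPKM. Of the most abundant adult globin genes, Hba-a1 and Hbb-b1 overlapped between genotypes, and Hbb-b2 was lower in both knockout libraries without passing the test. Hba-a1 averaged 152172 ± 23362 FPKM in wild type and 133697 ± 16324 FPKM in knockout (SD, n = 2). Hbb-b1 averaged 28891 ± 4312 and 27383 ± 2061 FPKM, and Hbb-b2 17198 ± 3262 and 12093 ± 449.8 FPKM. Hba-a2 averaged 254 ± 67.3 and 235 ± 46.2 FPKM, Hbb-bs 59.1 ± 17.6 and 53.4 ± 1.87 FPKM, and the embryonic Hba-x 135 ± 32.7 and 122 ± 14.8 FPKM. Hbq1b averaged 297 ± 74.3 and 192 ± 50.6 FPKM (unadjusted p = 0.0437), and Ahsp, the alpha globin chaperone, 1487 ± 412 and 886 ± 414 FPKM. Hbb-bt and Hbb-bh1 were too low to test, at no more than 0.2 and 1.03 FPKM. The alpha pair and the beta genes are near-identical copies, and the split of reads between the copies is uncertain.

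For heme synthesis, Alas2, the erythroid enzyme of the committed step, averaged 3922 ± 285 FPKM in wild type and 2983 ± 216 FPKM in knockout (log2 change −0.39, limma adjusted p = 0.486). Alas2 was among the 12 of 20 heme genes that were lower in both knockout libraries, while 1 gene was higher in both. In the membrane list 10 of 23 genes were lower in both knockout libraries and 3 were higher in both. Slc4a1 and Ermap, an erythroid membrane-associated protein, passed when adjusted over the list alone (limma adjusted p = 0.0213 for each) and not over all genes (0.166 for each). Ermap stood at 117 and 111 FPKM in wild type and 74.2 and 66.8 FPKM in knockout. The tetraspanin gene Tspan33 averaged 322 ± 11.6 and 338 ± 4.96 FPKM and did not pass the test.

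**Figure D2:**
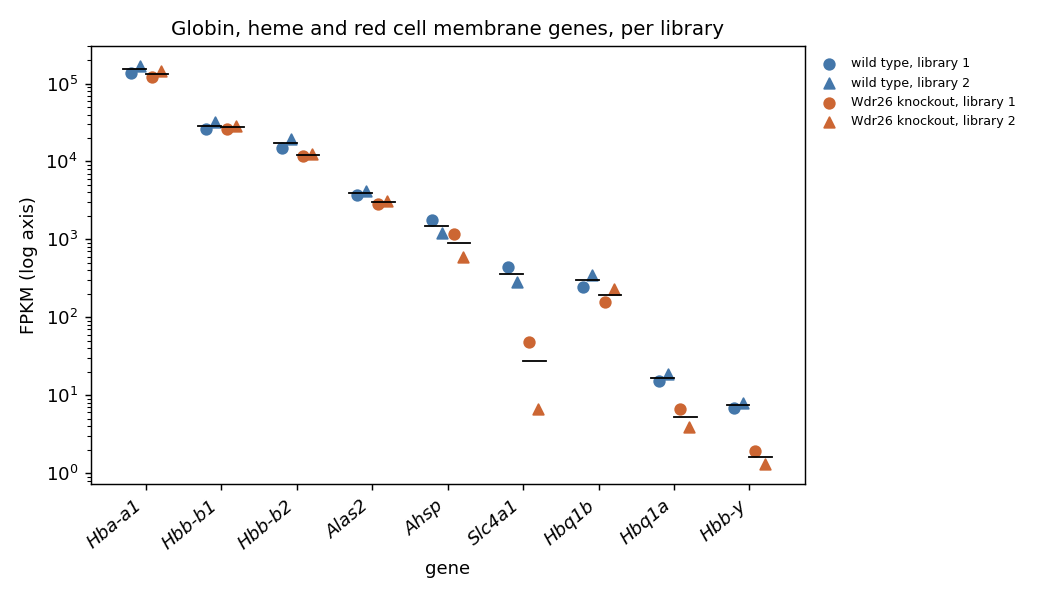
FPKM of 9 globin, heme and red cell membrane genes in each library, on a log axis, with wild type in blue, knockout in orange, library 1 as circles, library 2 as triangles and black lines at the mean of each genotype. Slc4a1 shows the widest distance between genotypes, 436 and 285 FPKM against 48.6 and 6.70 FPKM, while the points of Hba-a1 and Hbb-b1 overlap.

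The erythroid transcription factors and the genes of enucleation and late erythroblasts were lower by smaller amounts. Their medians were −0.092 over 18 genes and −0.064 over 19 genes (−0.17 and −0.14 with median-centred values). Camera gave adjusted p = 0.022 and 0.02 for these lists, and adjusted p = 0.569 and 0.558 with an estimated correlation. Of the transcription factors 3 were higher and 7 lower in both knockout libraries than in both wild-type libraries. The most abundant, Gata1, overlapped between genotypes, and averaged 476 ± 18.9 FPKM in wild type and 488 ± 52.1 FPKM in knockout, while its partner Zfpm1 (FOG1), at 347 ± 17.3 and 402 ± 6.51 FPKM, was higher in both without passing the test. Epor, the erythropoietin receptor, averaged 320.1 ± 9.79 and 254 ± 40.9 FPKM, and the small GTPase gene Rac2 118 ± 0.170 and 146 ± 1.74 FPKM, neither past the test over all genes. The call on the transcription factors ended without wild-type library 2 (adjusted p = 0.0822) or knockout library 2 (adjusted p = 0.197, median 0.022), under quantile normalization (0.091) and without the filter (0.102). That on the enucleation list ended without wild-type library 2 (adjusted p = 0.0822), knockout library 1 (0.106, median −0.014) or knockout library 2 (0.114).

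Cell division genes were also lower in the knockout. The mitosis list, from cyclins to spindle and kinetochore genes, had a median log2 change of −0.17 over 24 genes, with 10 lower in both knockout libraries and 0 higher in both (camera adjusted p = 3.85e-07, and adjusted p = 0.558 with an estimated correlation). Its most abundant members, given as values, were the ubiquitin-conjugating enzyme gene Ube2c, at 139 ± 9.87 FPKM in wild type and 127 ± 28.6 FPKM in knockout, and the proliferation marker Mki67, at 77.8 ± 7.40 and 70.0 ± 2.74 FPKM. The median of the list was −0.29 without knockout library 1 and −0.11 without knockout library 2.

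DNA replication genes had a median of −0.18 over 24 genes and the replication-dependent histones a median of −0.22 over 30 genes. Both lists differed more between libraries of a genotype than between genotypes. All 24 replication genes and 24 of the 30 histone genes were lower in library 2 than in library 1 in both genotypes. Pcna, the sliding clamp of DNA replication, stood at 117 and 72.6 FPKM in the wild-type libraries and at 105 and 49.6 FPKM in the knockout libraries. Slbp, which binds histone mRNA, stood at 59.6 and 42.6 FPKM and at 55.3 and 40.6 FPKM. Camera gave adjusted p = 0.00683 for replication and 2.25e-05 for histones, and adjusted p = 0.779 and 0.771 with an estimated correlation. The replication call ended without the filter on low genes (adjusted p = 0.0716). Without knockout library 2 the direction turned, to a median of 0.34 for replication (adjusted p = 0.0121) and 0.22 for histones (adjusted p = 0.993), and without wild-type library 1 the replication median was 0.21 (adjusted p = 0.986). The histone gene Hist1h2ah passed when adjusted over the list alone, at 2.95 and 3.13 FPKM in wild type and 0.63 and 1.00 FPKM in knockout, but histone genes share near-identical sequence and their values are uncertain. The most abundant of them, Hist1h1c and Hist1h4m, averaged 235 ± 92.6 and 181 ± 29.4 FPKM in wild type and 251 ± 122 and 203 ± 38.3 FPKM in knockout.

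Among metabolic genes, cholesterol synthesis had a median of −0.13 over 22 genes and glycolysis a median of −0.19 over 19 genes (camera adjusted p = 0.000239 and 0.000584, and adjusted p = 0.572 and 0.558 with an estimated correlation). Insig1, which restrains the sterol-sensing machinery, averaged 76.7 ± 5.03 FPKM in wild type and 54.6 ± 7.11 FPKM in knockout (unadjusted p = 0.0163), and Fdps, which makes farnesyl diphosphate, 79.1 ± 12.1 and 74.3 ± 15.7 FPKM. The glycolytic enzyme genes Aldoa and Pkm, the most abundant of their list, averaged 3470 ± 727 and 1336 ± 257 FPKM in wild type and 3413 ± 917 and 1443 ± 131 FPKM in knockout. The cholesterol call ended without knockout library 2 (adjusted p = 0.0815, median −0.040), and its median ran from −0.29 without wild-type library 2 and −0.28 without knockout library 1 to −0.037 without wild-type library 1. The glycolysis call ended without wild-type library 2 (adjusted p = 0.107, median −0.10), and its median was −0.38 without wild-type library 1.

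Antigen presentation was the only called list that was higher in the knockout, with a median of 0.29 over 14 genes, 9 of them higher in both knockout libraries and 2 lower in both. Among all 10670 genes tested, without centring, 3195 were higher in both and 1149 lower in both. The list's mean level relative to all genes overlapped between genotypes, at −0.037 and 0.27 in wild type and 0.25 and 0.44 in knockout. Camera gave adjusted p = 0.0221, and adjusted p = 0.771 with an estimated correlation. Adjusted over the list alone, 5 members passed, all higher, and none passed over all genes. They were the immunoproteasome subunit genes Psmb8, Psmb9 and Psmb10 and the peptide transporter genes Tap1 and Tap2. Psmb8 stood at 3.43 and 5.67 FPKM in wild type and 9.60 and 14.1 FPKM in knockout, and Tap1 at 10.6 and 12.1 FPKM and 16.2 and 20.7 FPKM. Psmb9 stood at 1.59 and 2.09 FPKM and 3.36 and 3.54 FPKM. The most abundant members were B2m, which encodes the light chain of class I molecules, at 99.7 ± 15.2 and 113 ± 1.94 FPKM, and the class I gene H2-T23, at 93.8 ± 17.1 and 110.3 ± 32.6 FPKM. The call ended without wild-type library 1 (adjusted p = 0.254) or knockout library 2 (adjusted p = 0.235), and 10 of the 14 genes were higher in library 2 than in library 1 in both genotypes.

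**Figure D3:**
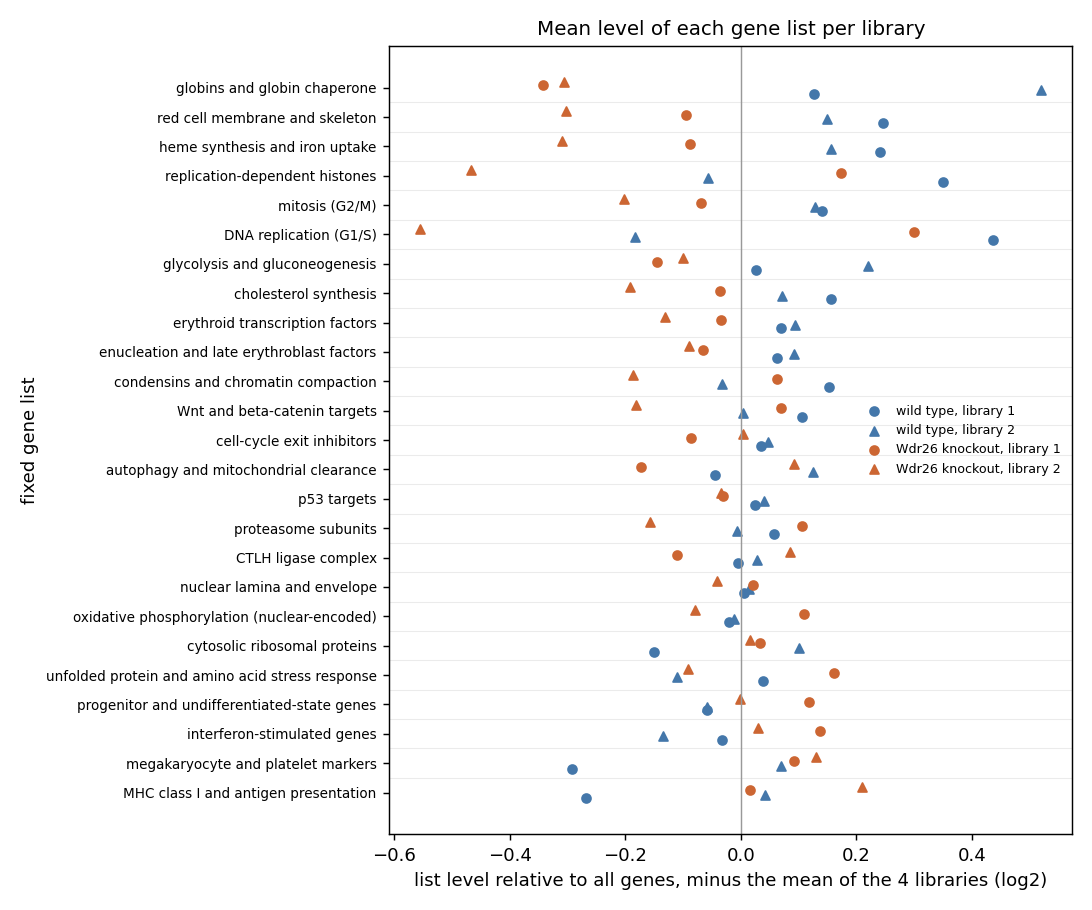
Mean log2(FPKM + 1) of each of the 25 fixed gene lists relative to all tested genes in each library, minus the mean of the 4 libraries, with wild type in blue, knockout in orange, library 1 as circles and library 2 as triangles. Globin, heme, membrane and mitosis lists have both knockout libraries left of both wild-type libraries. So do the transcription factor, enucleation, glycolysis, cholesterol, p53 target and cell-cycle exit lists. Interferon, progenitor and megakaryocyte lists have both knockout libraries right of both wild-type libraries, while the antigen presentation list overlaps between genotypes. The replication and histone lists separate library 1 from library 2.

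The partners of Wdr26 in the CTLH ligase did not change past the test as a list or singly. The list had a median of 0.12 and a mean of 0.049 over 11 genes, while camera gave the direction down against all genes (adjusted p = 0.844). The median was −0.0066 without wild-type library 2, −0.049 without knockout library 2 and 0.040 with median-centred values. Ranbp10, which can take the scaffold position of Ranbp9, averaged 139 ± 11.5 FPKM in wild type and 105 ± 11.6 FPKM in knockout (log2 change −0.40, unadjusted p = 0.0357, limma adjusted p = 0.397). Ranbp9 itself averaged 17.8 ± 0.460 and 21.3 ± 2.45 FPKM. The catalytic RING subunit genes Maea, Rmnd5a and Rmnd5b averaged 75.0 ± 0.269, 53.3 ± 2.98 and 21.7 ± 4.55 FPKM in wild type and 83.9 ± 1.61, 53.8 ± 7.51 and 23.4 ± 2.31 FPKM in knockout. Gid8 and Armc8 averaged 31.6 ± 3.45 and 4.25 ± 0.198 FPKM in wild type and 33.9 ± 1.48 and 3.85 ± 0.304 FPKM in knockout. The substrate receptor gene Gid4 averaged 11.7 ± 0.792 and 13.3 ± 0.290 FPKM, Ypel5 21.7 ± 1.58 and 24.9 ± 6.88 FPKM, Mkln1 15.8 ± 0.707 and 14.8 ± 1.40 FPKM, and the partner E2 enzyme gene Ube2h 21.1 ± 1.73 and 24.3 ± 5.56 FPKM.

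Nuclear lamina and envelope genes likewise did not pass as a list or singly. The median over 17 genes was −0.017 and the mean 0.052 (camera direction down, adjusted p = 0.678), with medians of 0.080 without wild-type library 1 and 0.078 without knockout library 2. The lamin genes Lmna, Lmnb1 and Lmnb2 averaged 156 ± 27.7, 18.8 ± 2.40 and 11.2 ± 2.53 FPKM in wild type and 130.4 ± 7.58, 15.9 ± 3.83 and 10.6 ± 3.05 FPKM in knockout. The lamin B receptor gene Lbr averaged 41.8 ± 4.36 and 36.0 ± 2.60 FPKM, and Tmpo 33.4 ± 6.07 and 25.98 ± 5.68 FPKM. Emd averaged 57.7 ± 2.91 and 65.0 ± 2.31 FPKM, Banf1 37.0 ± 4.28 and 37.0 ± 14.5 FPKM, Lemd2 26.8 ± 3.80 and 35.8 ± 7.57 FPKM, Lemd3 8.81 ± 0.0283 and 7.94 ± 0.898 FPKM, and Ankle2 12.1 ± 1.24 and 11.9 ± 0.120 FPKM. Among genes that link the nucleus to the cytoskeleton, Sun1 averaged 24.2 ± 0.841 and 28.5 ± 4.22 FPKM, Sun2 14.3 ± 1.58 and 16.2 ± 2.60 FPKM, Syne1 1.78 ± 0.643 and 2.86 ± 0.700 FPKM, and Syne3 4.87 ± 0.424 and 5.91 ± 0.721 FPKM. Syne2 was listed at 0 in all 4 libraries. The pore gene Nup210 averaged 12.1 ± 1.56 and 16.9 ± 2.998 FPKM (unadjusted p = 0.0441, limma adjusted p = 0.418), Tor1a 22.4 ± 1.62 and 25.5 ± 3.39 FPKM, and Tor1aip1 11.2 ± 0.276 and 10.6 ± 0.240 FPKM.

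Progenitor genes were not called as a list (median 0.12 over 11 genes, camera adjusted p = 0.212), and their median was 0.044 with median-centred values. The transcription factor genes Fli1 and Gata2 passed when adjusted over the list alone. Fli1 stood at 6.28 and 5.87 FPKM in wild type and 10.5 and 11.3 FPKM in knockout, and Gata2 at 2.49 and 2.53 FPKM and 4.11 and 4.52 FPKM. The abundant members Lyl1 and Spi1 averaged 73.5 ± 4.33 and 48.4 ± 7.18 FPKM in wild type and 64.4 ± 15.8 and 48.5 ± 12.7 FPKM in knockout. The p53 targets had a median of −0.011 and a mean of 0.0076 (camera direction down, adjusted p = 0.506). Their median was above 0 with any single library left out (0.017 to 0.091) and without the filter (0.014). Among them, Sesn2 is a stress-induced inhibitor of growth signalling that is also in the stress response list. Sesn2 stood at 17.1 and 17.3 FPKM in wild type and 31.9 and 34.1 FPKM in knockout. Perp was listed at 1.24 and 1.16 FPKM in wild type and at 0 in both knockout libraries. Sesn2 and Perp passed when adjusted over the p53 list alone and not over all genes.

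Megakaryocyte and platelet markers, the only list of another cell type with enough tested genes, had a median of 0.20 over 7 genes (camera adjusted p = 0.207). The list passed without wild-type library 2 (adjusted p = 0.0126, median 0.35), and its median was 0.048 without wild-type library 1. Over all 4 libraries camera gave adjusted p = 0.779 with an estimated correlation. Treml1, a platelet receptor gene, stood at 0.40 and 0.77 FPKM in wild type and 3.66 and 3.55 FPKM in knockout, and Nrgn at 27.0 and 23.4 FPKM and 44.5 and 34.3 FPKM, both past the test when adjusted over the list alone. Itga2b (integrin alpha IIb) averaged 224 ± 12.1 and 238 ± 3.32 FPKM, and Pf4 (platelet factor 4) 40.5 ± 25.05 and 29.6 ± 11.7 FPKM. Neutrophil and monocyte markers had 2 tested genes, Cebpa at 8.32 ± 2.33 and 11.7 ± 1.69 FPKM and Prtn3 at 3.24 ± 0.502 and 9.51 ± 3.77 FPKM. Markers of mast cells, of lymphocytes and of fibroblasts and endothelium reached at most 0.75, 0.36 and 0.66 FPKM in any library. The genes named because they passed only within their own list were chosen after their values were seen.

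The other lists did not pass under the main settings. Interferon-stimulated genes had a median of 0.24 over 13 genes (camera adjusted p = 0.093). Bst2 averaged 17.1 ± 3.88 FPKM in wild type and 25.6 ± 4.06 FPKM in knockout, and Isg20 16.5 ± 0.283 and 24.05 ± 4.89 FPKM. The median of the interferon list was 0.11 without wild-type library 2, 0.38 without wild-type library 1 and 0.066 without the filter. This list passed with median-centred values (adjusted p = 0.0385) and under quantile normalization (0.0484), where the ribosomal protein and oxidative phosphorylation lists passed too (0.022 and 0.0448), all higher. With an estimated correlation, without such scaling, these lists had adjusted p = 0.779 for interferon, 0.809 for ribosomal proteins and 0.865 for oxidative phosphorylation. Medians were −0.076 for condensins and chromatin compaction (camera adjusted p = 0.0838), 0.18 for cytosolic ribosomal proteins (0.134) and 0.12 for oxidative phosphorylation (0.41). They were 0.093 for the unfolded protein and amino acid stress response (0.633) and −0.11 for cell-cycle exit inhibitors (0.426). The cell-cycle exit median was above 0 without wild-type library 1 (0.056), knockout library 1 (0.12) or knockout library 2 (0.089). It was −0.068 without wild-type library 2. The oxidative phosphorylation median ran from −0.0075 (without knockout library 1) to 0.21 (without knockout library 2). That of the stress response ran from −0.014 (without wild-type library 2) to 0.29 (without wild-type library 1). The condensin list passed without wild-type library 2 (adjusted p = 0.00608, median −0.17) and without knockout library 1 (0.00775, median −0.24), and its median was above 0 without wild-type library 1 (0.042) and without knockout library 2 (0.076). The condensin list also passed with the library block on median-centred values, a fit added after the data were seen (camera adjusted p = 0.0448). With an estimated correlation over all 4 libraries it had adjusted p = 0.779. Ribosomal proteins passed without wild-type library 2 (adjusted p = 2.63e-05), interferon-stimulated genes without wild-type library 1 (0.0218) and the stress response without knockout library 2 (0.0106, and adjusted p = 0.865 with an estimated correlation over all 4 libraries), all higher. Abundant members of these lists, given as values, were the linker histone gene H1f0 at 631 ± 106 FPKM in wild type and 561 ± 137 FPKM in knockout, Rps4x at 2765 ± 294 and 2956 ± 154 FPKM, Cox4i1 at 407 ± 9.67 and 482 ± 61.6 FPKM, the chaperone gene Hspa5 at 237 ± 51.8 and 255 ± 86.0 FPKM, and Btg2 at 237 ± 45.7 and 216 ± 60.0 FPKM. For autophagy, proteasome subunits and Wnt targets the medians were 0.0087, 0.0046 and 0.066, while camera gave the direction down against all genes, whose median was 0.067 (adjusted p = 0.25, 0.389 and 0.493). Bnip3, a mitophagy receptor gene of the autophagy list, averaged 193 ± 41.5 FPKM in wild type and 134 ± 24.9 FPKM in knockout (unadjusted p = 0.0467, limma adjusted p = 0.429). Autophagy passed as lower without wild-type library 1 (adjusted p = 0.0215) and without knockout library 2 (0.0106), and the proteasome without knockout library 1 (0.0174). With an estimated correlation over all 4 libraries they had adjusted p = 0.779 and 0.865. Of the 31 proteasome genes 5 were higher in both knockout libraries, among them Psmd4 at 288 ± 11.5 and 336 ± 18.4 FPKM, and 1 was lower in both, while Psmb4, at 383 ± 16.0 and 410 ± 106.6 FPKM, overlapped. Over all 10670 genes tested, without centring, 3195 were higher in both knockout libraries and 1149 lower in both, so these counts show no rise particular to the proteasome. Myc, a member of the Wnt and progenitor lists, stood at 56.1 and 31.5 FPKM in the wild-type libraries and at 66.8 and 25.7 FPKM in the knockout libraries.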

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

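The tests that joined the library block to median-centred values or to the stricter filter were chosen after the results were seen. All 10 called genes kept their direction under every alternative in which they were tested, and Wdr26 ranged from −2.67 to −2.46 on the log2 scale. Without the filter no gene passed in limma (1692 at an unadjusted p under 0.05), and Wdr26, at −2.55, had an adjusted p of 0.0675. Its lowest adjusted p in limma, 3.86e-118, came from the library block with the stricter filter. Block fits and fits without 1 library leave 1 residual degree of freedom per gene. Their p-values and counts of genes therefore rest almost wholly on variance shared across genes. A mean of at least 5 FPKM left 2 genes, testing against a log2 change of 1 left 3, and leaving out the globin genes gave 21. Leaving out single libraries, where a lone library is assumed to vary like the other genotype, gave between 0 genes (without either wild-type library) and 720 (without knockout library 1, with 314 without knockout library 2), and Wdr26 values between −2.63 and −2.46, with −2.51 and −2.58 and adjusted p of 0.0682 and 0.0549 without wild-type libraries 1 and 2. Genes that reach 1 FPKM only in wild type, such as Muc13, fail the filter once a wild-type library is left out. For the other changes the cause was not tested. At these depths a value near 0.1 FPKM rests on few fragments, which limits the precision of Muc13 and Slc22a17 in the knockout.

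With the library number as a block, 1863 genes passed (1388 higher and 475 lower), the 10 genes among them. With median-centring the block gave 1391 (773 higher and 618 lower), and with the stricter filter 1511 (1118 higher and 393 lower). The pairing has no source in the labels: the difference between libraries 1 and 2 of wild type correlated with that of the knockout at r = 0.61 across the 10670 genes, which are not independent replicates. On simulated data with 200 changed genes the block called on average 94.1 genes, 0.2 of them false, with noise shared by number. With independent noise it called 7.7, 0 of them false. The simulated noise was independent between genes, with a fixed part shared by number. Its false calls therefore do not carry over to the 1863 genes.

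Of the 11 list calls, 0 held in camera with an estimated correlation and 0 with directional fry (lowest adjusted p 0.558 and 0.526). With an estimated correlation few lists could pass, since the degrees of freedom come from the residuals of 4 libraries. The enucleation, glycolysis and transcription factor calls were lost at estimated correlations of only 0.023, 0.032 and 0.039, beside the preset 0.01. For these lists the loss therefore cannot tell correlated list members from low power. Estimated correlations of the other called lists ran from 0.086 for the membrane list to 0.98 for replication, with 0.20 for heme, 0.23 for mitosis and 0.35 for globins. For those lists the p-values at the preset of 0.01 may be too small, while low power also affects their loss. In fry for either direction 2 lists passed, the enucleation and megakaryocyte lists (adjusted p 0.0242 for each). The globin, heme, membrane and mitosis calls held under each scaling, filter, pseudocount, block and left-out library, except that the globin list cannot be tested with its genes left out. Leaving out 1 library of a genotype lets part of the difference between its libraries 1 and 2 enter the comparison of genotypes. For replication genes that difference, number 2 minus number 1, had medians of −0.73 in wild type and −0.96 in knockout. The cause of the number difference stays open. Several medians turned direction when a library was left out. The ranges were −0.70 to 0.34 for replication (0.21 without wild-type library 1, 0.34 without knockout library 2), −0.63 to 0.22 for histones (0.22 without knockout library 2), −0.19 to 0.022 for erythroid transcription factors (0.022 without knockout library 2), −0.12 to 0.12 for autophagy (−0.023 without wild-type library 1, −0.12 without knockout library 2), −0.16 to 0.15 for the proteasome (−0.16 without knockout library 1) and −0.69 to 0.66 for Myc (0.66 without knockout library 2). Over all settings 187 values of named genes gained and 37 lost the threshold in the same direction, as did 12 and 43 list values. A further 73 of 1749 values of named genes and 49 of 422 list medians or directions changed sign with neither value past the threshold, and are counted here as not reversed. Some of the 422 could not move. Camera kept its own trend in every fit, so limma without the trend changed no list value. In camera with an estimated correlation and in fry the medians were those of the main fit, so at most directions could change.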

Other observations

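Several abundant genes outside the fixed lists differed at least 2-fold without passing the test over all genes. They are the 5 most abundant named genes in each direction, chosen after their values were seen. Higher in both knockout libraries were Ccdc92 (46.8 and 50.7 FPKM in wild type, 89.6 and 106 FPKM in knockout), Arrb2, which encodes beta-arrestin 2 (29.5 and 32.4, then 65.5 and 81.9 FPKM), and Alox5ap, which encodes the activating protein of 5-lipoxygenase (28.7 and 33.3, then 54.1 and 72.3 FPKM). S100a6, a calcium-binding protein gene, stood at 14.1 and 17.3 FPKM in wild type and 33.7 and 51.7 FPKM in knockout, and Rogdi at 17.8 and 17.3 FPKM and 34.2 and 38.1 FPKM. Lower in both were Atp2b4, the plasma membrane calcium pump gene expressed in red cells (129 and 140.3 FPKM in wild type, 40.3 and 57.0 FPKM in knockout), and Asic4 (18.8 and 17.7, then 10.9 and 7.01 FPKM). Fam132b, which encodes the iron-regulating hormone erythroferrone and overlaps another gene, stood at 30.6 and 17.8 FPKM in wild type and 17.1 and 6.81 FPKM in knockout. Apol11b and Apol11a, neighbours in a family of similar genes whose split of reads is uncertain, stood at 177 and 86.1 FPKM and at 20.7 and 8.70 FPKM in wild type, and at 75.6 and 18.9 FPKM and 6.93 and 1.44 FPKM in knockout. The platelet receptor genes Pear1 (5.45 and 6.98, then 17.2 and 23.2 FPKM) and P2rx1 (6.77 and 12.0, then 20.1 and 24.9 FPKM), also singled out after their values were seen, were higher in both knockout libraries (limma adjusted p = 0.0803 and 0.205).

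Libraries numbered 2 differed from those numbered 1 in several gene groups. Replication genes had median log2 differences, number 2 minus number 1, of −0.73 in wild type and −0.96 in knockout, and 24 of 24 were lower in number 2 in both. For histones the medians were −0.43 and −0.67, with 24 of 30 lower in both, and for proteasome subunits −0.15 and −0.29, with 27 of 31 lower in both. Globins had medians of 0.35 and 0.11, with 7 of 10 higher in both, and ribosomal proteins 0.21 and 0.028, with 22 of 39 higher in both. Whether the number difference itself differs between genotypes was not tested.

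Of the tests below, those on the globin share, on the maturation stage, on the growth stage of the libraries numbered 2 and on the other splits were chosen after the results were seen.

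The globin, heme and red cell membrane lists were lower in the knockout, which could come from the scaling of FPKM, from gene properties, from chromosome copy number or from the stage of the cultures. A smaller globin share in the knockout would raise the other FPKM values alike, not lower them, whereas the heme list was lower by −0.40 relative to all genes (a gap between genotypes of 0.24 against at most 0.22 within one), and its median was −0.26 with globins left out. For an earlier stage of maturation the values point both ways: the mitosis list was lower, by −0.27 relative to all genes (a gap of 0.20 against at most 0.13 within a genotype), while the progenitor list was higher in both knockout libraries, by a gap of 0.057 against at most 0.12 within a genotype, and Gata2 and Fli1 passed within it. The X chromosome's median, at −0.048 against that of all genes, lay beyond the 95% limit of 0.039 from permuted chromosomes. Taking off each chromosome's median still left the median of the 53 list members at −0.26 (95% bootstrap interval −0.36 to −0.20). For the 50 members with a length and GC content, taking off a fit on both left −0.26 (−0.39 to −0.19, from −0.26 before). The intervals come from resampling list members, not libraries. Whole-chromosome medians cannot detect gains or losses of chromosome parts. A reduced erythroid program in the knockout stays open as a hypothesis. So do an earlier stage and untested clonal differences, including the copy number of chromosome parts. The calls on the globin, heme, membrane and mitosis lists were lost in camera with an estimated correlation (adjusted p = 0.558 for each), where few lists could pass.

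The agreement of the same-numbered libraries could come from library chemistry or from the state of the cultures. Over the 10104 genes with a length and GC content, taking off a fit on both left the correlation across genes between the number differences of wild type and knockout at r = 0.73 (95% bootstrap interval 0.71 to 0.74, from r = 0.68 before in these genes), which argues against those properties as the whole source. Relative to all genes, replication genes were lower in number 2 in both genotypes, by −0.62 in the genotype with the smaller difference, while the genotypes differed by at most 0.37 within a number. The mitosis list differed by −0.011 in wild type and −0.13 in knockout, less than the 0.33 between genotypes, so a different growth stage of the cultures numbered 2 stays open and is not shown by these values. A shared day of harvest or of library preparation was not tested, since the labels name none.

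The 4 libraries can be parted into 2 and 2 in 3 ways, which are too few for a share under 0.05. The real split gave 10 genes past the threshold and the highest other split 1 gene. The split by number called 0 genes in limma, with 1503 at an unadjusted p under 0.05.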
